A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

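Transcript levels in 2 groups of yeast samples, 3 of the nab2-1 mutant and 3 of the wild type, had been measured on Affymetrix yeast expression arrays, with 1 array per sample. The labels give both strains as W303-1A derivatives grown exponentially in rich medium, total RNA as the starting material and biotin-labelled cRNA from the standard one-cycle protocol as the target. The deposited table holds log2 values for 10928 probe sets, and GCOS, RMA and limma are the tools per the submitters' processing notes, without versions or order. The values lay on a log2 scale and were used as deposited, with no further normalization in the reported results. Over the tested genes the array medians were near-equal, from 10.27 to 10.30. Over all probe sets they were 7.09 to 7.14 in nab2-1 and 6.81 to 6.88 in the wild type. No detection calls were used here, because the table holds 1 value per probe set and array.

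Genes were taken from the annotation of the platform and updated through the RefSeq gene table of the S288C reference assembly, which changed 12 symbols. Of the probe sets, 5498 had 1 Saccharomyces cerevisiae gene, 1 had several genes and was not named, 1746 belonged to the other yeast on the array, 213 were control and reporter probe sets, and 3470 had no gene in the annotation used here. A gene with more than 1 probe set took the one with the highest mean over the 6 arrays, which left 5449 genes. The chromosome of a gene was read from its systematic name, and the reference table gave gene spans and the order of neighbouring genes; no coordinates were taken from it, because the sources used here name no genome build for the array. The 95th percentile of the other-species probe sets, 4.27 on the log2 scale, served as a level for probe sets without target RNA, and 51 genes (0.936%) had a mean under it. Where 1 group's mean lay under that level, a fold is given as at least the bright group's mean over it. The number of arrays limits the precision of each value; the median standard error of a difference was 0.063.

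The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05 on the adjusted p. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 52 lists tested of 55 written from general knowledge; the lists of mitochondrially encoded genes and of small nucleolar and nuclear RNAs had 0 measured genes, and the MATalpha-specific list had 4. Members of each list were also counted past the threshold over all genes and adjusted over the list alone. The genes of each of the 16 chromosomes were tested in the same way. Spearman correlations across genes set the difference against gene span and mean signal, beside the other splits of the 6 arrays. These tests, the lists and most alternatives were fixed before the data were examined.

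Named genes followed a fixed rule. It took NAB2 and the strain marker genes, the 12 largest rises and 12 largest falls among genes past the threshold whose 3 nab2-1 values all lay on 1 side of the 3 wild type values, up to 4 genes with the largest changes in the direction of each list that passed, and up to 2 genes of other lists described. TRP1 had no probe set among the tested genes and was not analysed here. A gene named outside this rule is given as chosen after its values were seen.

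The alternatives were quantile, median and cyclic loess normalization over the tested genes, array weights, trend and robust variance estimation, the replicate number as a block, filters on dim probe sets, every probe set counted, other thresholds, camera with an estimated correlation, limma's fry, and each array left out in turn. Scaling to 35 probe sets of spiked Bacillus poly(A) controls, lowering each gene by the median of its chromosome and leaving out 3 chromosomes were added after the data were seen. GC content was not analysed, because no genome sequence was used here. On simulated values for the 5449 genes of this comparison, with 200 changed genes, the gene test recovered 44% of the genes changed by 0.25 on the log2 scale, 88% at 0.5 and 100% at 1 and at 2, and 13 of its 179 calls were false (7.26%). In the same simulation design, both of the 2 shifted lists and 0 of the 49 unshifted ones were called, as were the 1 shifted and 0 of the 15 unshifted chromosomes, each shifted by 0.5. Far more genes, 3672, passed in the data than were changed in the simulation. It therefore does not show how specific the list test is on the data. There 0 lists were called with an estimated correlation and 43 with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.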

Results

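Gene expression was compared between the nab2-1 mutant of budding yeast and a wild type strain. NAB2 encodes an essential nuclear protein that binds the poly(A) tails of mRNAs and takes part in their export. Per the labels, the mutant strain lacked the chromosomal NAB2 gene, replaced with HIS3, and carried the nab2-1 allele on a centromeric LEU2 plasmid. Each group had 3 samples, and 5449 genes were tested. Pearson correlations between arrays across probe sets of the tested genes ran from 0.994 to 0.998 within a group and from 0.940 to 0.947 between groups. The median SD of a gene was 0.078 in nab2-1 and 0.065 in the wild type on the log2 scale. Differences below are log2 signal in nab2-1 minus wild type ± SE, with n = 3 arrays per group, and adjusted p-values are limma's after Benjamini-Hochberg adjustment. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

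The RNA of the mutated gene was measured first. NAB2 had a log2 signal of 13.71 ± 0.12 (SD) in nab2-1 and 12.36 ± 0.07 in the wild type, a rise of 1.35 ± 0.07, or 2.56-fold (adjusted p = 4.9e-06). Where the probes lie relative to the nab2-1 lesion is not given in the sources used here, so this signal does not check the labels. Among the marker genes, HIS3, which marks the deletion, fell by 0.39 ± 0.06 (adjusted p = 0.00059), and CAN1, the arginine permease gene, fell by 0.91 ± 0.08 (adjusted p = 3.7e-05). LEU2, the plasmid marker, differed by 0.21 ± 0.10 (adjusted p = 0.11), ADE2 by 0.05 ± 0.05 (adjusted p = 0.36) and URA3 by -0.10 ± 0.11 (adjusted p = 0.47), none past the threshold. Of the array's own control probe sets for URA3, those for the 5' end and the middle of URA3 differed by -3.97 (adjusted p = 1.2e-10) and -3.55 (adjusted p = 6.2e-10), and that for its 3' end by 0.17 (adjusted p = 0.50). Without nab2-1 replicate 1 the LEU2 difference was 0.30 (adjusted p = 0.022), and scaled to the spiked controls that of HIS3 was -0.11 (adjusted p = 0.54).

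To determine whether whole chromosomes differed between the strains, the genes of each chromosome were set against all other genes. Genes of chromosomes I, XI and XVI were higher in nab2-1 almost throughout. Relative to the median of the other 13 chromosomes, the median gene was 1.80-fold higher on chromosome I, 1.84-fold on XI and 1.82-fold on XVI, with array values of 0.84 ± 0.08, 0.86 ± 0.01 and 0.87 ± 0.01 (log2, SD, n = 3). Of 90 tested genes on chromosome I, 76 rose and 2 fell; on XI 263 of 293 rose and 10 fell; on XVI 384 of 424 rose and 12 fell. The medians of the other 13 chromosomes lay between -0.14 and -0.08. The shift ran along the whole of each chromosome, as the 39 blocks of at least 20 neighbouring genes on I, XI and XVI had medians from 0.53 to 0.94, while the 226 blocks elsewhere lay between -0.40 and 0.29. The camera adjusted p was 1.3e-15 for I, 7.1e-33 for XI and 7.4e-40 for XVI, and 7 other chromosomes were called lower, since each is compared with all remaining genes. With an estimated correlation the adjusted p was 0.091 for I, 0.00041 for XI and 0.00054 for XVI, so the call for I was lost.

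**Figure D1:**
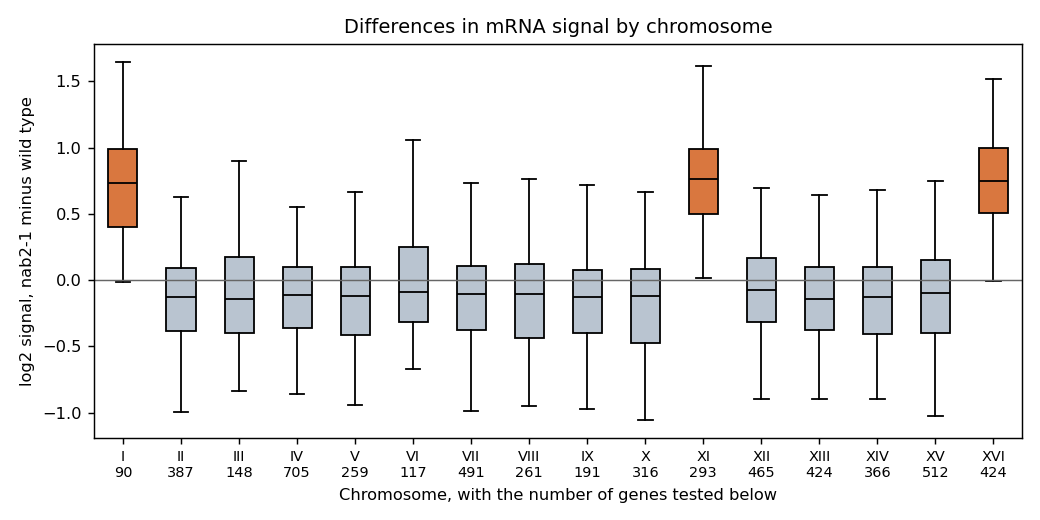
Log2 differences of the tested genes (vertical axis) on each of the 16 chromosomes (horizontal axis). Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles. The medians of chromosomes I, XI and XVI, in orange, were 0.73, 0.77 and 0.75, and all others lay between -0.14 and -0.08.

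Over the whole genome, 1644 genes rose and 2028 fell in nab2-1, together 67.4% of the genes tested, and 322 of the risen and 216 of the fallen genes changed at least 2-fold. On chromosomes I, XI and XVI 723 of 807 genes rose (89.6%), while elsewhere 921 of 4642 rose (19.8%) and 2004 fell (43.2%). The excess of falls elsewhere went with a median of -0.11 over those genes. Relative to chromosome medians, which places the median of each chromosome at 0, 1370 of the 4642 were higher and 1470 lower. The genes with the largest rises were FRE7, a metal reductase gene (3.78 ± 0.09, or 13.8-fold), SPO19, a sporulation gene (3.73 ± 0.18), BAG7 (3.37 ± 0.13), FAT3 (3.23 ± 0.12), SRL3 (3.09 ± 0.08) and HSP30, a plasma membrane stress protein gene (3.05 ± 0.07). CSR2 followed at 2.91 ± 0.05, the copper transporter gene CTR1 at 2.59 ± 0.06, the protein kinase gene YPK2 at 2.56 ± 0.06, YKL070W at 2.53 ± 0.20, SET6 at 2.51 ± 0.25 and HAL1 at 2.49 ± 0.06. Of these 12 genes, 8 lie on chromosomes I, XI and XVI, as do 198 of the 322 genes at least 2-fold higher. Relative to chromosome medians SPO19 was at 2.98, FAT3 at 2.47, SRL3 at 2.32 and CSR2 at 2.16. CTR1 was then at 1.84, YKL070W at 1.76, SET6 at 1.76 and HAL1 at 1.74. The order of the 12 genes changes with that setting, as YPK2, on chromosome XIII, was at 2.70.

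The 12 largest falls, 0 of them on those 3 chromosomes, included genes of zinc and phosphate uptake. ZPS1, a zinc-regulated cell-surface gene, fell by 5.16 ± 0.05 (35.7-fold), and the zinc transporter gene ZRT1 fell by 3.83 ± 0.09 (14.2-fold). The phosphate transporter gene PHO84 fell by 4.99 ± 0.13 (31.8-fold), and the acid phosphatase gene PHO5 fell by 3.18 ± 0.13. SPL2, which acts in the switch between phosphate transporters, fell from 9.19 ± 0.33 to 5.19 ± 0.18 (SD). PHM6 was at the level of the other-species probe sets in nab2-1, and its signal was at least 5.31-fold lower than in the wild type (adjusted p = 3.7e-06). The other large falls had differences of -3.28 ± 0.20 for VEL1, -3.16 ± 0.14 for NCA3, -2.93 ± 0.04 for the S-adenosylmethionine synthetase gene SAM2, -2.83 ± 0.09 for PNS1, -2.82 ± 0.09 for the stress sensor gene WSC4 and -2.66 ± 0.08 for OPI3, which acts in phosphatidylcholine synthesis. The split between directions depended on the scaling. With the arrays scaled to the spiked poly(A) controls, the median of all genes moved from -0.05 to 0.22, and 2132 genes were higher and 621 lower (77.4% higher against 44.8%). The amounts of spiked control per sample are not stated in the sources used here. The mean of these controls had an SD of 0.24 over the wild type arrays and 0.035 over the nab2-1 arrays. The hybridisation controls bioB, bioC, bioD and cre differed by medians of -0.75, -0.45, -0.17 and -0.027. The offset of the spiked controls therefore need not reflect the amount of RNA. Without the genes of chromosomes I, XI and XVI, 907 were higher and 1986 lower (31.4% higher), but that setting keeps the negative median of the remaining genes. Relative to chromosome medians 1614 genes were higher and 1731 lower (48.3% higher).

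**Figure D2:**
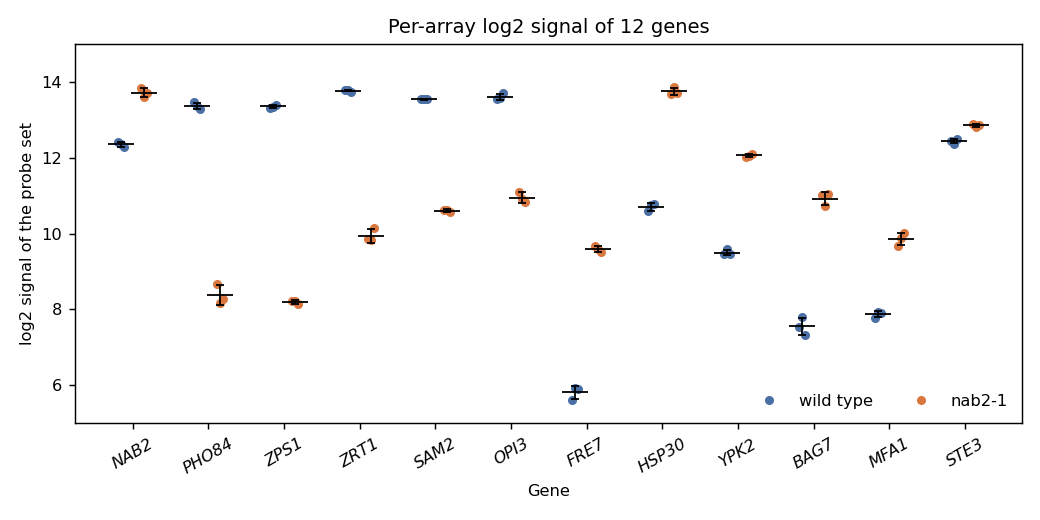
Log2 signal of the probe set (vertical axis) for 12 genes (horizontal axis) in the 3 wild type arrays (blue) and the 3 nab2-1 arrays (orange), with the mean and SD as black lines. The signal of ZPS1 was 13.35 in the wild type and 8.20 in nab2-1, and that of NAB2 was 12.36 and 13.71.

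Gene lists were then tested for a shift against all other genes, and 13 of the 52 passed, 7 higher and 6 lower. Genes of the phosphate regulon were lower: 16 of 19 fell and 1 rose, and 16 fell and 2 rose adjusted over the list alone. PHO84, SPL2, PHO5 and PHM6 fell most. The camera adjusted p of this list was 0.0019, with adjusted p = 0.68 with an estimated correlation. Of 28 genes of methionine and sulphur metabolism, 19 fell and 6 rose, with the same counts adjusted over the list alone (adjusted p = 0.0060, and adjusted p = 0.68 with an estimated correlation). Besides SAM2, the methionine synthase gene MET6 fell by 2.37 ± 0.09, MET13 by 2.11 ± 0.07 and the methionine permease gene MUP1 by 1.99 ± 0.07. Of 13 genes of branched-chain amino acid synthesis and transport, 12 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00038, and adjusted p = 0.68 with an estimated correlation). Among them LEU1 fell by 2.07 ± 0.06, BAT1 by 1.44 ± 0.06, ILV3 by 0.76 ± 0.06 and OAC1, which lies on chromosome XI, by 1.49 ± 0.05 (-2.25 relative to the median of that chromosome). Per the labels the nab2-1 allele came on a LEU2 plasmid. An effect of that marker on the branched-chain genes cannot be told apart from one of the allele. All 8 measured arginine synthesis genes fell, also adjusted over the list alone (adjusted p = 0.042, and adjusted p = 0.69 with an estimated correlation), led by ARG1 at -1.03 ± 0.09 and ARG4 at -0.77 ± 0.07, with ARG2 at -0.36 ± 0.06 and ARG8 at -0.30 ± 0.07. The arginine call was lost without wild type replicate 1 (adjusted p = 0.060), without wild type replicate 3 (0.059), relative to chromosome medians (0.067) and without the genes of the 3 chromosomes (0.083). Without the dimmest 25% of genes it was lost too (0.062), as was that of the methionine list (0.12). Scaled to the spiked controls, fewer genes of these lists were lower: 10 of the phosphate regulon (2 higher), 13 of the methionine list (6 higher), 6 of the branched-chain list, whose median moved from -0.57 to -0.30, and 2 of the 8 arginine synthesis genes, whose median moved from -0.30 to -0.022. Relative to chromosome medians 5 of the 8 arginine genes were lower.

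Genes of the general stress response and of trehalose and glycogen metabolism were also lower, with 34 of 47 down and 5 up, also adjusted over the list alone (adjusted p = 0.0022, and adjusted p = 0.79 with an estimated correlation). MSC1 fell by 2.16 ± 0.15, the catalase gene CTT1 by 1.96 ± 0.16, RTN2 by 1.82 ± 0.19 and the phosphoglucomutase gene PGM2 by 1.72 ± 0.19. Of 22 genes of the unfolded protein response, 15 fell and 2 rose, also adjusted over the list alone, with a median of -0.27 that was 0.0029 when scaled to the spiked controls (adjusted p = 0.042, and adjusted p = 0.76 with an estimated correlation). HRD3 and HRD1, genes of a ubiquitin ligase complex of the endoplasmic reticulum, fell by 0.95 ± 0.06 and 0.75 ± 0.08, EUG1 by 0.94 ± 0.07 and SEC63 by 0.71 ± 0.06. Scaled to the spiked controls, 22 genes of the general stress list were lower and 7 higher, and 8 of the unfolded protein response were lower and 4 higher. The unfolded protein response call was lost without wild type replicate 3 (adjusted p = 0.068) and without the dimmest 25% of genes (0.062). Heat shock protein genes showed no common direction as deposited, with 11 of 34 higher and 12 lower, also adjusted over the list alone (adjusted p = 0.65). Scaled to the spiked controls, 15 of them were higher and 3 lower, with a median of 0.26. HSP30 rose by 3.05 and BTN2 by 2.15 ± 0.06.

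Among the lists that were higher, all 7 measured MATa-specific genes rose, also adjusted over the list alone, with a median of 1.53 (adjusted p = 0.0010, and adjusted p = 0.68 with an estimated correlation). The a-factor genes MFA1 and MFA2 rose by 1.98 ± 0.09 and 1.54 ± 0.09, the agglutinin gene AGA2 by 1.57 ± 0.08 and the a-factor exporter gene STE6, on chromosome XI, by 1.53 ± 0.06, or 0.77 relative to the median of that chromosome. Of 21 pheromone response genes, 18 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00041, and adjusted p = 0.68 with an estimated correlation). PRM3 rose by 2.38 ± 0.12, PRM4 by 1.85 ± 0.06, FIG1 by 1.81 ± 0.10 and PRM6 by 1.35 ± 0.11. PRM3 and PRM4 lie on chromosome XVI, and relative to chromosome medians PRM3 was at 1.63, PRM4 at 1.10, FIG1 at 1.93 and PRM6 at 1.49. Of 42 meiosis and sporulation genes, 24 rose and 7 fell, and 25 rose and 7 fell adjusted over the list alone (adjusted p = 0.0027, and adjusted p = 0.68 with an estimated correlation). SPS1 rose by 1.72 ± 0.14, the cohesin gene REC8 by 1.52 ± 0.07 and SPR3 by 1.47 ± 0.15, and SPR28, at the other-species level in the wild type, was at least 3.06-fold higher. REC8 lies on chromosome XVI and was at 0.77 relative to its median. Without the dimmest 25% of genes, 1 MATa-specific gene and 3 meiosis genes were left, too few to test, while 12 pheromone response genes were left and that call was kept (adjusted p = 0.015).

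Of 101 ribosome biogenesis genes, 54 rose and 4 fell, also adjusted over the list alone, with a median of 0.20 (adjusted p = 1.1e-05, and adjusted p = 0.68 with an estimated correlation). RRP15 rose by 1.30 ± 0.10, DHR2 by 1.26 ± 0.08, TIF6 by 1.15 ± 0.05 and NAN1 by 1.15 ± 0.05, all 4 on chromosomes XI and XVI; 18 of the 101 genes of the list lie on I, XI and XVI. Relative to chromosome medians RRP15 was at 0.55, DHR2 at 0.50, TIF6 at 0.40 and NAN1 at 0.39, and 69 of the list were higher and 4 lower. Of 38 proteasome genes, 17 rose and 2 fell, also adjusted over the list alone, with a median of 0.10 (adjusted p = 0.027, and adjusted p = 0.68 with an estimated correlation). RPN4, the transcription factor gene of the proteasome, rose by 1.00 ± 0.07 and PRE2 by 0.83 ± 0.06, while RPN7 and RPT1 rose by 0.53 ± 0.04 and 0.45 ± 0.05. PRE2, RPN7 and RPT1 lie on chromosomes XI and XVI and were at 0.076, -0.22 and -0.32 relative to the chromosome medians. Of 15 thiamine genes 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.042, and adjusted p = 0.68 with an estimated correlation), with PET18 at 1.55 ± 0.09, THI22 at 1.27 ± 0.07, THI21 at 1.08 ± 0.09 and THI6 at 0.81 ± 0.05. THI22, THI21 and THI6 lie on chromosome XVI and were at 0.52, 0.33 and 0.060 relative to its median. Of 17 genes of silent and subtelomeric families 10 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.042, and adjusted p = 0.68 with an estimated correlation). PAU4 was higher by 2.17 ± 0.06, PAU3 by 1.78 ± 0.24, PAU7 by 1.66 ± 0.09 and PAU8 by 1.65 ± 0.14, but these near-identical genes share probes and cannot be assigned singly. PAU7 and PAU8 are on chromosome I and were at 0.92 and 0.91 relative to its median. The list test counted the PAU genes as separate genes. The 3 genes of the list that fell were all COS genes. COS12, COS7, COS6, COS10, COS2 and COS4 were at -0.91, -0.60, -0.29, -0.13, -0.10 and -0.02. The chromosomes of COS10, COS2 and COS4 had medians of -0.12, -0.13 and -0.09, so these genes differed little from their chromosomes. COS8 and COS9 were at 0.28 and 0.49, and COS9 lies on chromosome XI. The rise was thus mainly that of PAU genes. The thiamine call was lost without wild type replicate 3 (adjusted p = 0.053) and the subtelomeric call without wild type replicate 1 (0.056) or under cyclic loess (0.053); without the dimmest 25% of genes they were lost too (0.24 and 0.29).

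**Figure D3:**
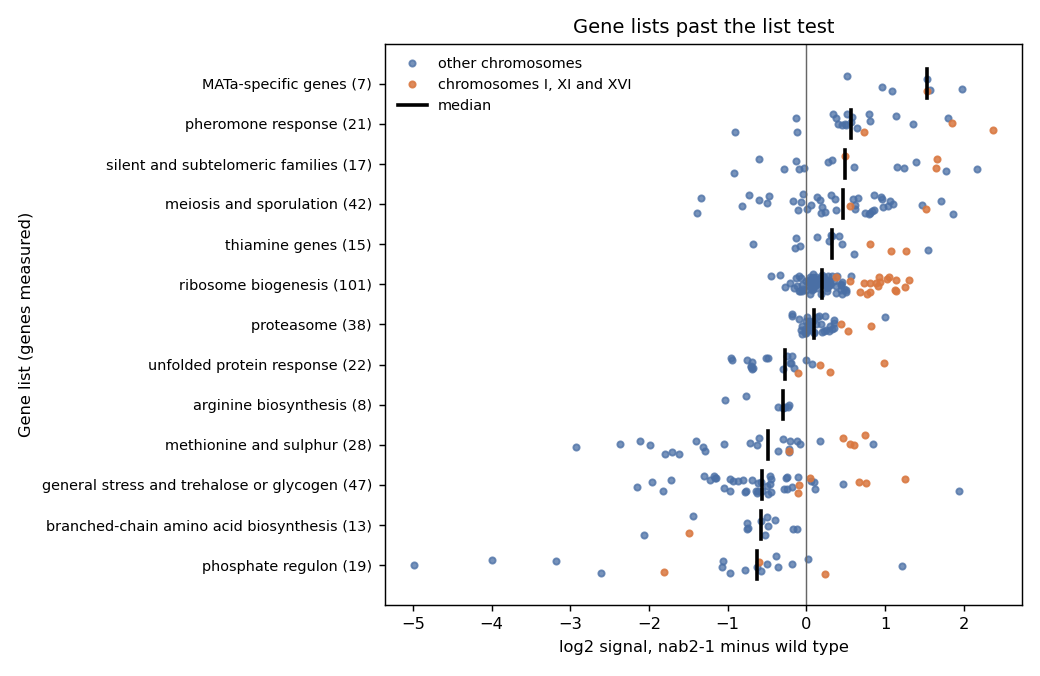
Log2 differences (horizontal axis) of the genes in the 13 lists that passed the camera test (vertical axis, with the number of genes measured), 1 point per gene and a black bar at the median. Orange points are genes on chromosomes I, XI and XVI. The medians ran from -0.63 for the phosphate regulon to 1.53 for MATa-specific genes, and that of the unfolded protein response, -0.27, was 0.0029 when scaled to the spiked controls.

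The lists closest to the known role of Nab2 did not pass. Of 33 mRNA export genes 11 were higher and 9 lower, also adjusted over the list alone, and their median of -0.05 differed in sign from the mean of 0.13 and from the test (adjusted p = 0.50) and from the median of 0.23 when scaled to the spiked controls. The export receptor gene MEX67 rose by 0.85 ± 0.05 and YRA2 by 1.00 ± 0.06, and both lie on the shifted chromosomes, where they were at 0.10 and 0.24 relative to the chromosome median. Of 21 nuclear exosome and TRAMP genes 7 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.36). Relative to chromosome medians 13 were higher and 3 lower (camera adjusted p = 0.089). Scaled to the spiked controls 13 were higher and 0 lower. NRD1, a termination factor gene, rose by 0.69 ± 0.07, and NAB3 rose by 0.36 ± 0.06 but was at -0.39 relative to chromosome XVI. Of 21 cleavage and polyadenylation genes 12 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.10), with YTH1 at 0.87 ± 0.08 and the poly(A) polymerase gene PAP1 at 0.85 ± 0.05. YTH1 and PAP1 lie on chromosomes XVI and XI and were at 0.12 and 0.085 relative to the chromosome medians, and in the list 6 were then higher and 4 lower. Of 19 RNA polymerase III genes 9 were higher and 5 lower, also adjusted over the list alone (adjusted p = 0.38), with RPC82 at 1.08 ± 0.07 and RPC37 at 0.83 ± 0.05, on chromosomes XVI and XI, where they were at 0.33 and 0.064 relative to the chromosome median. Of 129 ribosomal protein genes 4 were higher and 33 lower, 3 and 10 adjusted over the list alone (adjusted p = 0.15), and their median of -0.07 was 0.20 when scaled to the spiked controls and 0.02 relative to chromosome medians. RPL22B fell by 0.68 ± 0.07 and RPS22B by 0.36 ± 0.05. The median, mean and test also differed in sign in the lists of heat shock proteins, haploid-specific genes, the TCA and glyoxylate cycles, intron-containing genes, oxidative phosphorylation, cytoplasmic mRNA decay and the nuclear pore, none of which passed.

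Relative to chromosome medians, a setting chosen after the data were seen, 4 more lists passed. Of 29 G1/S cell cycle genes 7 were higher and 18 lower, also adjusted over the list alone (adjusted p = 0.086), and 0 higher and 19 lower relative to chromosome medians (adjusted p = 0.00017), with 8 and 8 when scaled to the spiked controls. Of 19 DNA damage response genes 11 were higher and 2 lower, or 13 and 2 adjusted over the list alone (adjusted p = 0.066), and 13 and 1 relative to chromosome medians (adjusted p = 0.0020). Of 13 galactose and maltose genes 7 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.083), and 7 and 1 relative to chromosome medians (adjusted p = 0.0073), with 6 and 5 under quantile normalization. These 3 lists also passed without the genes of the 3 chromosomes. Of 29 ergosterol and fatty acid synthesis genes 6 were higher and 16 lower, also adjusted over the list alone (adjusted p = 0.16), and 3 and 13 relative to chromosome medians (adjusted p = 0.048), and their median of -0.17 was 0.10 when scaled to the spiked controls, with 7 higher and 4 lower. On the values as deposited, the camera adjusted p with an estimated correlation was 0.74 for DNA damage response and 0.68 for the other lists of this paragraph. An estimated correlation was not run relative to chromosome medians.

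Whether the change in signal depended on gene span or on expression level was tested across genes, which are not independent replicates. Spearman's rho over 5449 genes was -0.013 with gene span and -0.033 with mean signal. Other splits of the 6 arrays gave absolute values of up to 0.11 for span and 0.066 for signal, so neither relation exceeded what regrouping the arrays gave.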

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

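The tests of the array splits were planned; those on chromosomes I, XI and XVI, on ribosomal RNA and on the MATa-specific genes were chosen after the results were seen. Control and reporter probe sets, and probe sets without a gene name, take no part in the comparison of genes, and several of them differed between the groups. Of the reporter probe sets on the array, 4 were higher in nab2-1, with measured log2 differences of 10.28, 9.63, 6.20 and 1.64 (limma adjusted p from 2.3e-15 to 1.2e-06, n = 3 per group); the annotation used here gives them no gene. The first 3 had wild type means of 3.53, 3.41 and 3.34, under the level of the other-species probe sets, 4.27, so they are given as at least 745-fold, 435-fold and 38.5-fold higher, and the last had 6.41. Among 3470 probe sets with no named gene, 22 were at least 2-fold higher and 10 at least 2-fold lower in nab2-1. Only 400 of the 3470 lay above the level of the other-species probe sets in at least 1 group, so most had little signal to compare.

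Chromosomes I, XI and XVI were higher in nab2-1 over their whole length. Scaling of whole arrays takes no account of chromosomes. The smallest gap over the other 13 was therefore bound to change little under cyclic loess and quantile normalization. It was still 0.83 or more there, which gives no test of scaling. A limited range of signal does not account for the gap, since it was 0.71 or more in each of 4 bins of mean signal. Regulation of a limited set of genes or of 1 segment is argued against by the lowest of the block medians, 0.53, above the highest elsewhere, 0.29. All 39 blocks of these chromosomes lay above every block of the others, which is consistent with extra copies of the 3 chromosomes in the nab2-1 strain, a hypothesis found and tested on the same data. DNA was not measured, and whether such copies would come from the mutation or from the history of this strain stays open.

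All 8 probe sets for 18S and 5 of the 8 for 25S ribosomal RNA were higher in nab2-1, although mRNA is what the array is meant to report. The 8 probe sets for 18S rRNA rose by a median of 2.36, and 5 of the 8 for 25S rRNA passed, with a median of 1.47 over the 8, while the 5.8S rRNA probe set differed by 0.32 (adjusted p = 0.43). The 25S difference depended on the probe set. Those for its middle and 5' end rose by 1.76 and 1.23, while that for its 3' end was at 14.15 in nab2-1 and 14.18 in the wild type. The others that did not pass differed by 0.18 and 0.0028, at wild type means of 12.76 and 14.36. Whether probe sets this bright could still rise was not tested. The 18S level was 13.33 ± 0.16 (SD, n = 3) in nab2-1 and 10.93 ± 0.92 in the wild type, and the lowest nab2-1 array, at 13.15, lay above the highest wild type array, at 11.51. Broken RNA would raise 3' over 5' signal. Over 7 mRNAs the change was 0.024 to 0.25, a rise in each, with a median of 0.053. URA3 was left out, because its 5' signal differed by -3.97 between the strains. These values argue against a large difference in breakage but not a small one. The median rise over the 16 probe sets for 18S and 25S was 1.90 as deposited and 2.18 when scaled to the spiked controls. That scaling raises all nab2-1 values, so it could not show whether scaling made the rise. More rRNA with poly(A) tails, which the labelling step would copy, may be the source and was not tested.

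Of the 7 MATa-specific genes only 1 lies on I, XI and XVI, so a higher dose of those chromosomes could not directly raise the list. Relative to chromosome medians its median was 1.22, but that setting could change little for this list. An indirect effect of the shifted chromosomes on genes elsewhere was not tested. The labels name W303-1A, a MATa strain, yet MATalpha-specific genes had high signal in both groups. If the strains were MATalpha, MATa cells among the nab2-1 cells would lower the MATalpha-specific genes. The median difference of those genes was 0.32, though -0.20 relative to chromosome medians. An admixture of MATa cells cannot be told apart from a change within each cell. The level of the MATa-specific genes in MATa cells is not known from these arrays, and a small share of cells might suffice.

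The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split called 1644 genes higher and 2028 lower, and it was the 1 split of the 10 to reach either count, as the highest of the others was 0 (10 to 51 genes at an unadjusted p under 0.05 in limma). For gene lists, 2 of the 10 splits gave as many as the real 13, and the highest of the others gave 16. For chromosomes, 1 split, the real one, reached 10, and the highest other gave 4. Each of the other splits mixes arrays of both groups. The real difference then adds to the spread within its groups and stays in part in its contrast. Counts from those splits therefore do not measure what chance alone would give.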

How the results depend on the processing

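The alternatives relating to chromosome medians, to leaving out 3 chromosomes and to the spiked controls were chosen after the data were seen. Of the 1644 genes higher and 2028 lower, 322 and 216 remained at a log2 difference of at least 1, because the threshold is stricter. Without the genes of chromosomes I, XI and XVI, where fewer genes were tested, 907 were higher. Scaled to the spiked controls, which raises all nab2-1 values, 621 were lower. That scaling also adds the spread of those controls, an SD of 0.24 over the wild type arrays, where the median gene SD was 0.065. Leaving out each array in turn gave 1499 to 1681 higher and 1838 to 2012 lower. The NAB2 signal rose by 1.29 to 1.63 under all settings run. The other settings kept both counts within 1.5 times. Against 13 lists as reported, 0 were called with an estimated correlation (3 at an unadjusted p under 0.05), 43 with fry and 6 without the dimmest 25% of genes, 16 relative to chromosome medians, 15 without the genes of the 3 chromosomes, 14 under cyclic loess, 16 with a trend in camera, which adds translation factors, DNA damage response and ribosomal proteins, and 10 to 14 with each array left out. Against 10 chromosomes, 3 were called with an estimated correlation, 16 with fry and 4 when scaled to the spiked controls, and 10 to 11 with each array left out; I, XI and XVI were higher in each of these settings except that chromosome I was not called with an estimated correlation. Except where a fold or filter defines the change, the cause was not tested. The replicate numbers pair no samples: deviations of same-numbered arrays correlated at -0.19, 0.19 and -0.14, and not every array correlated best with its own number, so they share only a number. With the replicate number as a block, 1582 genes were higher and 1932 lower, with 14 lists and 11 chromosomes called. Spearman's rho with gene span was 0.00022 under cyclic loess, -0.028 without the dimmest 25% of genes and -0.028 to 0.0037 with each array left out; with mean signal it was -0.012, 0.016 and -0.039 to -0.027. Partial correlation given signal left the value for span within its spread. GC content was not run. The strain marker genes each had 1 probe set among those tested; of the control probe sets for URA3, that for the 3' end (0.17) was not past the threshold either, and those for the 5' end (-3.97) and the middle (-3.55) were. Of the named genes, relative to chromosome medians NAB3 reversed to -0.39, HTS1 to -0.14, RPN7 to -0.22, RPT1 to -0.32, STE3 to -0.34 and NOT5 to -0.029, since they lie on shifted chromosomes. URA3, not past the threshold, was at 0.022 relative to its chromosome and 0.18 when scaled to the spiked controls, -0.17 to 0.023 with each array left out and positive only without nab2-1 replicate 1; HTZ1 was at 0.0054 when scaled to the spiked controls. Of 149 named genes other than NAB2, 124 kept their call relative to chromosome medians and 16 lost it, and 138 kept and 8 lost it when scaled to the spiked controls. Of the genes, 51 had signal under the level of the other-species probe sets, where small differences have little meaning.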

Other observations

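The gene groups in this part were chosen after their values were seen, so their counts describe these arrays and are not independent tests. Genes under Ino2 and Ino4, the activators of phospholipid synthesis, were lower together: 11 of 14 fell and 2 rose, and relative to chromosome medians 13 were lower and 0 higher. The inositol synthase gene INO1 fell by 2.20 ± 0.07 (log2, SE, n = 3 per group), OPI3 by 2.66 ± 0.08, the phosphatidylserine genes PSD1 and CHO1 by 1.83 ± 0.06 and 1.72 ± 0.08, the inositol transporter gene ITR1 by 1.44 ± 0.05, while the choline transporter gene HNM1 was at -1.38 ± 0.07 and CHO2 at -1.02 ± 0.05. CKI1, CPT1 and EPT1, of the pathway that makes phospholipids from choline and ethanolamine, fell by 1.58, 1.66 and 1.57. The fatty acid synthase genes FAS1 and FAS2, on chromosomes XI and XVI, rose by 0.28 and 0.35 but were at -0.48 and -0.41 relative to the chromosome medians.

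Of 12 targets of Zap1, the activator of zinc uptake, 10 fell and 1 rose, among them ZPS1 and ZRT1, ZAP1 itself by 1.77 ± 0.06, ADH4 by 1.35 ± 0.05 and ZRT2 by 1.30 ± 0.07, while IZH2 rose by 0.34 ± 0.06. All 4 targets of Mac1, the activator of copper uptake, rose: FRE7 by 3.78 ± 0.09, CTR1 by 2.59 ± 0.06, FRE1 by 1.40 ± 0.08 and CTR3 by 0.88 ± 0.05. The wider list of zinc and copper genes, written before, had 5 of 15 higher and 8 lower, also adjusted over the list alone, and did not pass (adjusted p = 0.50); its median of -0.27 was 0.0034 when scaled to the spiked controls. The list of the iron regulon, also written before, had 15 of 27 higher and 11 lower, also adjusted over the list alone, and did not pass (adjusted p = 0.38). Scaled to the spiked controls it had 15 higher and 3 lower.

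Some values differ from what the strain names would lead one to look for. W303-1A is a MATa strain, yet the MATalpha-specific genes STE3, SAG1, MF(ALPHA)1 and MF(ALPHA)2 had mean log2 signals of 12.44, 13.15, 13.91 and 12.26 in the wild type arrays and 12.86, 12.97, 14.13 and 12.74 in nab2-1. HO, the mating-type switching endonuclease gene, was at 10.61 in the wild type and fell by 2.37 ± 0.06. The control probe sets for the 5' end and the middle of URA3 were lower in nab2-1 by 3.97 and 3.55, while that for its 3' end differed by 0.17, so the 3' minus 5' signal was 3.61 in nab2-1 and -0.53 in the wild type. Reporter probe sets with wild type means of 3.53, 3.41 and 3.34 had means of 13.81, 13.03 and 9.54 in nab2-1. The annotation used here gives them no gene. Per the labels HIS3 replaced NAB2 on the chromosome of the nab2-1 strain, which also carried a LEU2 plasmid. The strains thus differ in more than the nab2-1 allele, and the URA3 and reporter values may reflect further differences. The differences given for any gene may come in part from such other differences. The hybridisation controls bioB were lower in nab2-1 by a median of 0.75 with 9 of 9 past the threshold and bioC by 0.45 with 2 of 6, while bioD and cre differed by -0.17 and -0.027 with 0 of 6 each, and the spiked poly(A) controls differed by -0.30 with 0 of 35 past the threshold. These controls do not come from the yeast, so the handling of the arrays may have differed between the groups. Such a difference would coincide with the strains, and its part in the gene differences was not tested.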
